A study of Drosophila melanogaster with 4 samples.

How the data were processed

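GRO-seq libraries of adult ovaries of *Drosophila melanogaster* were used, 2 of control flies (mat>Luc) and 2 of Nup358 germline knockdown flies, each a separate biological repeat per the labels. Per the labels' protocols, run-on RNA was fragmented, its ends were repaired with polynucleotide kinase, and TruSeq small RNA libraries were sequenced as single reads of 50 bases. The submitters' processing notes name cutadapt, Bowtie2, RSEM and the dm3 build, without versions or roles. Each of the 4 deposited files listed the distinct trimmed read sequences of 1 library, 18 to 50 bases long, with the count of reads for each, and paired no sequence with a gene. The deposited counts were used unnormalised.

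The files held 26481812 and 18223866 reads in the controls and 24542062 and 27952610 in the knockdown, as 7037510, 5813186, 8973874 and 10377053 distinct sequences. Reads with an undetermined base were left out. Reads of 50 bases that ended in the first 3 to 8 bases of the adapter (TGGAATTC) lost those bases, which affected 15.1% and 12.9% of the control 50-base reads and 16.3% and 12.8% of the knockdown ones. This removal was decided after a first fit without it had been seen, and the reads as deposited served as an alternative.

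A genome sequence was not used. Instead, reads of at least 25 bases were mapped with bwa 0.7.19 (up to 2 mismatches, no gaps) to 26454 windows of 2000 bases upstream of transcription starts in dm3, which come with the Biostrings package 2.70.1. Merged, the windows covered 25.26 megabases, and their overlaps differed at 0 bases. Of 26261 window accessions, 25655 were matched to a gene in a RefSeq gene table of a later assembly, which gave names and gene lengths and no coordinates. A gene was taken to run from its start in dm3 over its length in that table, an assumption that could not be checked here. Windows upstream of 1 gene often lie inside another gene or a longer transcript of the same gene, and only such covered parts were measured. Of 12556 placed genes, 8267 had at least 200 covered bases on their own strand alone, with a median of 1608. A read was counted for a gene when it had 1 best place with no other within the mismatches allowed and its middle lay in the gene on the sense strand. Uniqueness was thus known within the windows only, and reads of gene parts outside the windows were not analysed here.

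Ribosomal RNA was assembled from the pooled reads with words of 20 bases, starting from short conserved sequences written from general knowledge, into a unit of 8285 bases and a 5S sequence of 145 bases. Transposon families were identified by 35 primer pairs and 12 protein sequences, also written from general knowledge, some of them after seeing which occurred in the pooled reads but before any comparison of the groups. A pair was accepted when the pooled reads joined both primers within 500 bases, and the amplicon was then extended by up to 400 bases on each side. A protein was accepted when at least 50% of its windows of 10 residues were encoded by pooled reads. Reads that encode at least 10 consecutive residues of an accepted protein were then counted for it. Accepted were 7 pairs for transposons (HeT-A, I-element, blood, roo, jockey, Max and 412), 2 pairs for control genes and 11 proteins, among them copia, 297, 17.6 and gypsy. The other accepted proteins were luciferase, GAL4, VP16, white, histones H3 and H4 and ubiquitin, and these were kept out of the fit. Strand was settled by the longest open reading frame of an assembled sequence, and was left open for HeT-A. A sequence of the Wolbachia surface protein gene was assembled in the same way and only its reads were counted. The identity of these sequences rests on the written sequences alone.

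Groups were compared with edgeR 4.0.16 (quasi-likelihood F-test, TMM factors, filterByExpr by group) in R 4.3.3, with group as the only term, genes and transposon families in 1 fit, and p values adjusted by the Benjamini-Hochberg method. A result was called at an adjusted p under 0.05. Intervals are 95% intervals. The 28 lists of genes were fixed before the data were examined, as were the tests, the rule for the genes named and the alternatives, apart from those stated as added. They were nuclear and cytoplasmic piRNA genes, nucleoporins, nuclear transport and SUMO, heterochromatin proteins, genes resident in heterochromatin, germline, follicle cell, muscle sheath, hemocyte with fat body and gut, neural and testis markers, heat shock, DNA damage and apoptosis, immune effectors, siRNA pathway, paused polymerase factors, germline dominant, soma dominant and intermediate transposons, replication dependent histones, ribosomal proteins, mitochondrial genes, nuclear oxidative phosphorylation, snRNA, snoRNA, tRNA and rRNA. Lists with at least 5 tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided), with an estimated correlation and fry as alternatives. With 4 libraries, the version with an estimated correlation can hardly call a list, so a list that it does not call is left undecided. The genes named were Nup358, the 10 largest rises and 10 largest falls past the threshold with groups that did not overlap and a mean of at least 5 CPM, up to 4 members past the threshold of each list (or the 2 most abundant where none passed), and the 5 features with the highest mean CPM. Other names are stated as singled out after their values were seen. Distinct sequences with at least 40 reads were tested with the same edgeR model without any reference, a test added later.

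Alternatives fixed beforehand were RLE and upper-quartile factors, library totals alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 50 counts in every library of a group, each library left out in turn, replicate number as a block, library sizes without the 20 features with most reads, reads in several genes counted for each, each position and strand counted once, adjusted p thresholds of 0.1 and 0.01, and glmTreat above 1.5-fold. Added after seeing the data were reads as deposited, exact matches only, all deposited reads as the library size, and transposon strands counted separately. For transposon families matched by protein, each distinct read sequence was counted once in place of each position and strand. Counts of positions can rise little where most covered bases are already counted, so they compress differences in abundant genes. Library sizes without ribosomal, small nuclear, transfer and mitochondrial RNA were not run, since the count table holds none.

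The edgeR and camera steps were tested on simulated data made with the dispersion of these libraries, after a first fit on the real counts had been made. Of 200 changed genes among 5917 simulated for the knockdown against control comparison, 3.0% were called at 1.5-fold, 61.2% at 2-fold and 100% at 4-fold, and 0 of 109 calls were false. In a simulated list shift, the shifted list was called and 1 of the unshifted lists among 17 was called. Genes were drawn independently at the trend of the dispersion. A smaller share of them was changed than the 14.5% called in the data, so these rates may not carry over. Permuting the libraries was not done, since 2 against 2 allows too few splits. Wilson intervals and floors cover counting error only, since reads carry no molecular identifiers, whereas intervals of log2 fold changes come from the edgeR fit and take in the spread between libraries.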

Results

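Global run-on sequencing (GRO-seq), in which isolated nuclei extend RNA polymerases that are already engaged and the nascent RNA is sequenced, was performed on adult ovaries of *Drosophila melanogaster*. The 4 libraries fell into 2 groups of 2 independent biological repeats. One group was the control (mat>Luc), and the other was a germline knockdown (GLKD) of Nup358, a nucleoporin of the cytoplasmic filaments of the nuclear pore. The genotype label of the knockdown libraries reads germline KO, whereas their titles and the design text say knockdown. Control replicates 1 and 2 held 26481812 and 18223866 reads, and knockdown replicates 1 and 2 held 24542062 and 27952610. Reads of the ribosomal RNA unit and 5S rRNA made up 53.5% and 48.6% of the control reads and 41% and 38.6% of the knockdown reads. Reads of at least 25 bases without a match in the sequences used made up 18.3% and 22.8% of the control reads, and 27.3% and 36.2% of the knockdown reads. The widest 95% Wilson interval of any of these shares spanned 0.046 percentage points, which covers counting error only. The reads counted here, those that matched 1 gene in the sense direction or 1 transposon family, came to 1774032 and 1665304 in the controls and 1966698 and 2092753 in the knockdown.

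**Figure D1:**
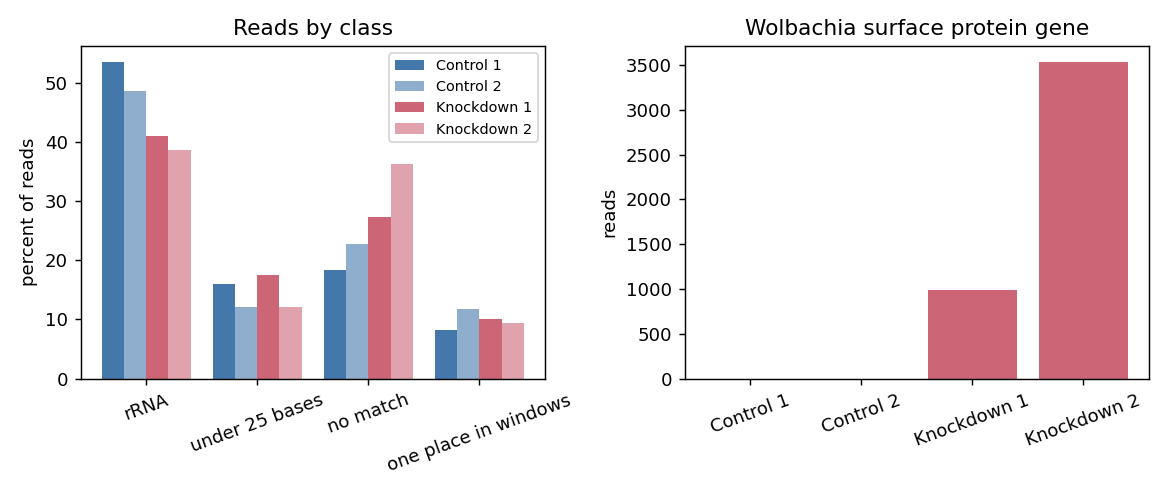
Left, share of reads in each library (percent, bars start at 0) that matched ribosomal RNA, were under 25 bases, matched nothing, or matched 1 place in the upstream windows. Right, number of reads of the Wolbachia surface protein gene in each library, which was 0 in both control libraries and 987 and 3537 in the knockdown libraries.

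The single contrast of the design asks how the run-on signal of transposons and genes in the ovary differs when Nup358 is depleted from germ cells; the series title names transposon silencing and piRNA biogenesis as its subject. Of 5906 genes tested, 463 rose and 393 fell in the knockdown at an adjusted p under 0.05 (edgeR quasi-likelihood test), which is 14.5% of the genes. Among them, 304 rose and 196 fell by at least 2-fold, and the median absolute log2 fold change was 1.07. The largest rises included Pepck1, a phosphoenolpyruvate carboxykinase of gluconeogenesis, and P5CS, an enzyme of proline synthesis. The largest falls included amd, which is related to dopa decarboxylase, and the chorion gene Cp7Fc. The groups did not overlap in 3591 genes (60.8%), where chance gives 33.3% with 2 libraries against 2. The common biological coefficient of variation was 0.166. Reads of the Wolbachia surface protein gene occurred in both knockdown libraries and in neither control library. An effect of infection or strain thus cannot be told apart from that of the knockdown for any gene or transposon family. Without knockdown replicate 2 the count of changed genes was 328, and with all deposited reads as the library size it was 407.

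Reads of the transgenes followed the labels of the groups where the groups differ. Sense reads of luciferase numbered 288 and 313 in the control libraries and 6 and 3 in the knockdown libraries. GAL4, the transcription factor of the driver, gave 98 and 50 sense reads in the controls and 42 and 51 in the knockdown. The activation domain VP16 gave 44 and 23 in the controls and 39 and 53 in the knockdown.

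Run-on signal of Nup358 itself did not differ between the groups by more than the spread of the replicates. It was measured over 2000 bases of the gene, on chromosome 3R of the dm3 build from 21082620 to 21084619 on the plus strand, which lie 7304 to 9303 bases downstream of its start. Control replicates 1 and 2 gave 419 and 232 counts per 1e6 counted reads (CPM), and knockdown replicates 1 and 2 gave 309 and 268. The log2 fold change was -0.17 with a standard error (SE) of 0.27 and an adjusted p of 0.682, and its 95% interval ran from -0.76 to 0.41. RNA interference acts on transcripts after they are made, so nascent signal does not measure the depth of the knockdown. Whether part of these reads came from finished RNA was not tested. Without control replicate 1 the log2 fold change was 0.31, and without control replicate 2 it was -0.55, neither past the threshold.

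Among 11 transposon families tested, 2 rose in the knockdown and 10 had a higher knockdown mean, with both strands counted together; without control replicate 2, 7 families rose, and without knockdown replicate 2, 1 rose. The I-element, a non-LTR retrotransposon active in the female germline, rose from 33 and 43 reads in the controls to 337 and 248 in the knockdown, a log2 fold change of 2.80 (SE 0.27, adjusted p = 0.000729). Its sequence was assembled from the pooled reads, and most I-element reads came from the knockdown. Control copies that differ from it by more than 2 mismatches would be missed. I-element reads without a mismatch numbered 27 and 35 in the controls and 311 and 224 in the knockdown. The LTR retrotransposon copia rose from 1743 and 1653 reads to 3255 and 3399, a log2 fold change of 0.83 (SE 0.23, adjusted p = 0.0381). Others did not pass the test. The LTR retrotransposon blood gave a log2 fold change of 0.74 (adjusted p = 0.0859), and the telomeric element HeT-A gave 0.54 (adjusted p = 0.0835). Values for roo and jockey were 0.56 and 0.41, and the only family with a lower knockdown mean was Max, at -0.46 (adjusted p = 0.164). Of the 7 germline dominant families tested, 2 rose over all features, 4 rose when adjusted over the list alone, and the median was 0.56. The camera test of this list gave an adjusted p of 0.03, which was 0.799 with an estimated correlation, and did not pass without control replicate 1 (median 0.42). In the soma dominant list, gypsy gave 0.32 (adjusted p = 0.364), and 0 of its 3 tested families passed in edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p under 0.05. The same tools called 0 of 1 family of the intermediate list, with 0 at an unadjusted p under 0.05. The 3 families whose names are plain numbers, named in the processing section, gave log2 fold changes of 0.29, 0.32 and 0.62 in the order in which they are named there, none past the threshold; the last of them passed without control replicate 2 (1.01) and with each position and strand counted once (0.66). The call for copia was lost without either knockdown library, with log2 fold changes of 0.81 and 0.82, with library totals (0.73) and with all deposited reads as the library size (0.70), while that of the I-element was kept without any 1 library, from 2.51 to 3.03.

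**Figure D2:**
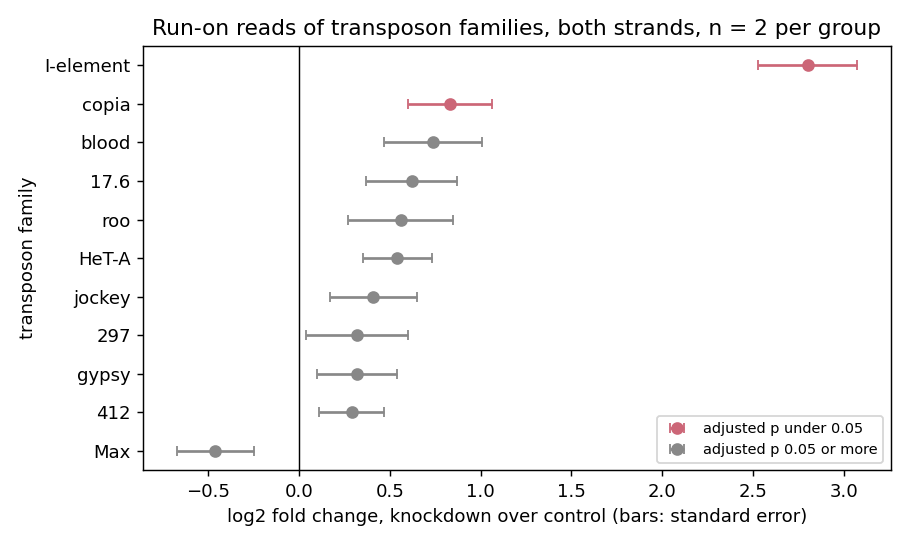
Log2 fold change (knockdown over control, horizontal axis) of the 11 transposon families tested, both strands together, with the standard error as bars and n = 2 libraries per group. The I-element lies at 2.80 and copia at 0.83, the 2 families past an adjusted p of 0.05, and Max lies below 0.

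When the strands were counted separately, a choice made after the data were seen, 4 strands passed the test. Reads antisense to the longest open reading frame of the assembled I-element sequence rose from 26 and 38 to 324 and 227 (log2 fold change 2.96, adjusted p = 0.000608). The sense strand of the I-element held 7 and 5 reads in the controls and 13 and 21 in the knockdown (log2 fold change 1.34, adjusted p = 0.106). Sense reads of copia rose with a log2 fold change of 1.04 (adjusted p = 0.017), and antisense reads of blood rose with 0.97 (adjusted p = 0.0396). Antisense reads of Max fell by 0.76 on the log2 scale (adjusted p = 0.0389).

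Follicle cell markers moved in both directions. Of 24 follicle cell markers tested, 5 rose, 8 fell and 11 did not pass; adjusted over the list alone, 6 rose and 11 fell. DESeq2 called 5 higher and 1 lower in this list, without Cp7Fc, Cp7Fa, Cp36 and Cp15, and limma-voom called 4 higher and 10 lower. The 7 tested chorion genes, which encode eggshell proteins made at the end of oogenesis, and the follicle cell protein gene Fcp3C were all lower in the knockdown. The median log2 fold change of these 8 genes was -2.26, and 7 of them fell, the exception being Cp18; Fcp3C and Cp18 were singled out after their values were seen. Cp15 (chromosome 3L, start at 8721581 in dm3) fell from 7210 ± 3210 to 1500 ± 1080 CPM (mean ± SD, n = 2), a log2 fold change of -2.26 (SE 0.51, adjusted p = 0.0179). Cp7Fc, Cp7Fa and Cp36, which lie together on the X chromosome, gave log2 fold changes of -3.11, -2.41 and -2.38. Without 1 library they ran from -5.49 to -2.26, from -4.08 to -1.66 and from -4.64 to -1.55. The 5 members that rose were the adhesion protein gene Fas3 (1.36), eya (1.13), the JAK/STAT ligand gene upd1 (1.11), sim (0.99) and pnt (0.89); they were singled out after their values were seen. The remaining member that fell was the yolk protein gene Yp3 (log2 fold change -1.44, adjusted p = 0.0282). The yolk protein genes Yp1 and Yp2 gave 0.42 (adjusted p = 0.572) and 0.09 and did not pass. Yp2 and Yp3 were singled out after their values were seen. With members moving both ways, the camera test of the list did not pass (adjusted p = 0.201). The 7 chorion genes and Fcp3C were also all lower in knockdown replicate 2 than in knockdown replicate 1, with a median log2 difference of -2.43. Of these 8, 1 was lower in control replicate 2 than in control replicate 1. With each position and strand counted once, Cp15 gave -0.37 and Cp36 gave -1.15 without passing, and Cp36 also did not pass with upper-quartile factors or the filter of 50 counts. Cp15 then held 521 and 567 positions in the controls and 510 and 385 in the knockdown, over 586 covered bases. Near that ceiling, this count cannot show a large difference. Cp15 also did not pass without knockdown replicate 2 (-1.68). Yp1 passed without control replicate 1 (1.34), while without control replicate 2 it gave -0.15.

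**Figure D3:**
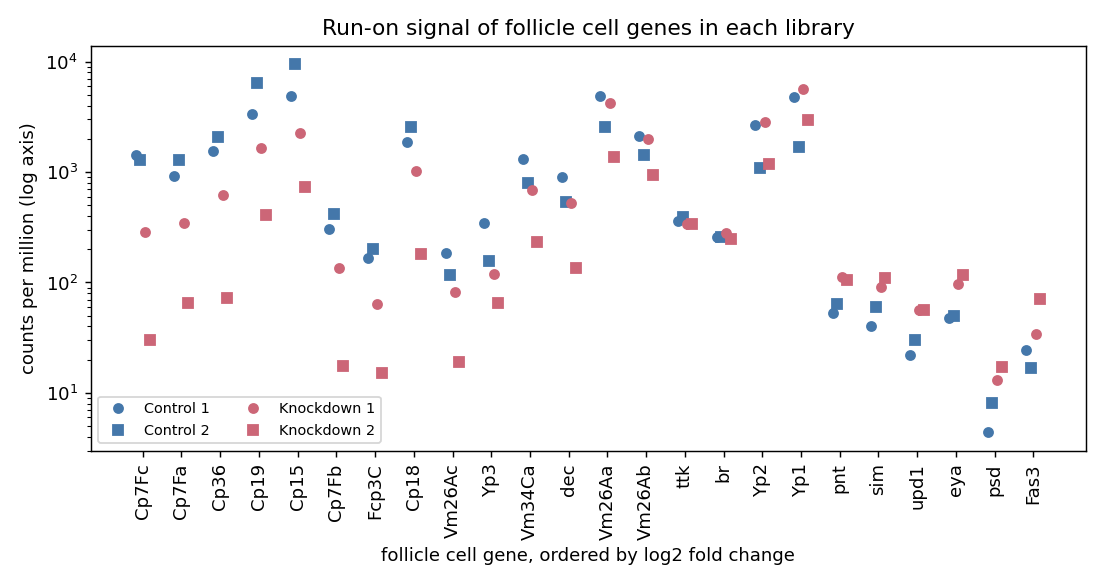
CPM (log axis) of the 24 tested follicle cell genes in each of the 4 libraries, ordered by log2 fold change; circles are replicate 1 and squares replicate 2, control in blue and knockdown in red. The chorion genes on the left are lowest in knockdown replicate 2, where Cp7Fc lies at 30.4 against 1430 and 1280 in the controls.

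Germline markers moved in both directions. Of 22 tested, 1 rose, 5 fell and 16 did not pass, and adjusted over the list alone 3 rose and 5 fell; the camera test gave an adjusted p of 0.779. The CPEB family RNA-binding protein gene orb rose from 401 ± 149 to 975 ± 149 CPM (log2 fold change 1.28, SE 0.28, adjusted p = 0.0157). The translational repressor gene nanos fell from 657 ± 29.7 to 320 ± 65.2 CPM (log2 fold change -1.04, SE 0.22, adjusted p = 0.0141). The early cell cycle gene plu gave a log2 fold change of -1.90, and the RNA helicase gene me31B gave -0.88. The other 2 members that fell, pgc and exu, gave -0.76 and -0.75 and were singled out after their values were seen. Without knockdown replicate 2, nanos (-0.85) and me31B (-0.83) did not pass, and me31B (-0.49) also did not without control replicate 2 or, at -0.96, without knockdown replicate 1. Without control replicate 1, plu gave -1.33 and did not pass, and me31B (-0.40) did not with each position and strand counted once.

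Genes of the piRNA pathway were largely without a change past the threshold. In the nuclear piRNA list, 0 of 12 tested genes passed in edgeR, DESeq2 or limma-voom, over all genes and in edgeR over the list alone, while 1 higher and 2 lower genes had an unadjusted p under 0.05 in edgeR. Its most abundant members, Hel25E and Trf2, gave log2 fold changes of 0.05 and 0.43. In the cytoplasmic piRNA list, 1 of 20 rose and 1 fell, and adjusted over the list alone 0 rose and 1 fell. They were tapas, a Tudor domain protein gene (log2 fold change 0.64, adjusted p = 0.0448), and csul, an arginine methyltransferase gene (-0.95, adjusted p = 0.0175). The camera test gave adjusted p = 0.941 for the nuclear list, where the median was 0.05 and the mean -0.02, and 0.999 for the cytoplasmic list. The mixed fry test, which takes in changes of either direction, gave an adjusted p of 0.043 for the nuclear list and 0.00645 for the cytoplasmic list. It called 12 of the 17 lists tested, so this was not particular to these lists. In the siRNA and microRNA list, 1 of 6 genes fell, Dcr-1, which processes microRNA precursors (log2 fold change -0.72, adjusted p = 0.0296); adjusted over the list alone 1 rose and 1 fell, and the camera test gave an adjusted p of 0.779. Without knockdown replicate 2, tapas (0.68), csul (-0.90) and Dcr-1 (-0.64) did not pass, and tapas (0.58) and Dcr-1 (-0.84) did not without knockdown replicate 1. Without control replicate 1, tapas gave 0.61 and did not pass, nor did it with upper-quartile factors (0.63), library totals (0.55), no filter (0.63), each position and strand counted once (0.24) or all deposited reads as the library size (0.51). The last of these settings also ended the calls for csul (-1.04) and Dcr-1 (-0.85), and DESeq2 did not call Dcr-1.

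Nucleoporin and heterochromatin genes leaned to lower values. Of 24 nucleoporin genes tested, 3 fell and 21 did not pass, with a list median of -0.24; adjusted over the list alone, 3 fell. Nup43, Nup37 and Nup75, members of the Y complex of the pore, gave log2 fold changes of -1.11, -0.91 and -0.74. The camera test of the list gave an adjusted p of 0.0458, which was 0.799 with an estimated correlation. Of 18 heterochromatin protein genes, 3 fell (4 adjusted over the list alone) with a median of -0.33. They were the histone demethylase gene Kdm4A (log2 fold change -1.15, SE 0.19, adjusted p = 0.00676), HP1c (-1.04) and HP5 (-0.70). Its camera test gave an adjusted p of 0.0458, which was 0.799 with an estimated correlation. In the nuclear transport and SUMO list, 1 of 22 genes fell over all genes and over the list alone, Tnpo-SR, an importin of SR splicing proteins (log2 fold change -1.07, adjusted p = 0.00842), and the camera test gave an adjusted p of 0.999. In the list of genes resident in heterochromatin, 1 of 6 tested genes rose over all genes and over the list alone, the phospholipase D gene Pld (log2 fold change 0.89, adjusted p = 0.0192). The list member bbc starts at 9382367 on chromosome 2R in dm3, far from Pld at 2129509. Whether every member lies in heterochromatin was not checked. The median of that list was 0.63 and its camera adjusted p was 0.0694. The downward shifts of the nucleoporin and heterochromatin lists did not pass without control replicate 1 (medians -0.09 and -0.18) or without knockdown replicate 2 (medians -0.24 and -0.27). Of the genes named here, Nup43 and Kdm4A passed without any 1 library, whereas without knockdown replicate 2 Nup37 (-0.68), Nup75 (-0.62), HP1c (-0.87), HP5 (-0.70) and Tnpo-SR (-0.98) did not, without control replicate 1 Nup37 (-0.80) and HP1c (-0.57) did not, and without knockdown replicate 1 Nup75 (-0.90), HP5 (-0.72) and Pld (0.76) did not. In DESeq2, 1 nucleoporin gene and 2 heterochromatin protein genes fell, and Nup37, Nup75 and HP5 did not pass; further settings under which both list shifts did not pass included the filter of 50 counts (medians -0.22 and -0.32), reads in several genes counted for each (-0.24 and -0.33) and all deposited reads as the library size (-0.33 and -0.44). The heterochromatin list also did not pass with reads as deposited (-0.32) or exact matches only (-0.29), and the nucleoporin list did not with each position and strand counted once (-0.16), where Nup75 and HP1c did not pass either; all deposited reads as the library size ended the calls for Nup37, Nup75, HP5 and Pld.

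Genes of ribosomal proteins mostly had positive log2 fold changes, few of them past the threshold. Of 66 tested, 65 had a positive log2 fold change with a median of 0.43, but 4 rose over all genes and 1 when adjusted over the list alone. RpL17, RpL35, RpS27 and RpL12 rose with log2 fold changes of 1.28, 1.06, 0.88 and 0.84. The camera test of the list gave an adjusted p of 3.56e-07, which was 0.799 with an estimated correlation, and directional fry gave 0.308. Without control replicate 2 the median was 0.19 and RpS27, at 0.65, did not pass. Without knockdown replicate 2 only RpL35 of these 4 passed, with RpL17 at 0.95, RpS27 at 0.83 and RpL12 at 0.83, and without knockdown replicate 1 RpS27 (0.90) and RpL12 (0.82) did not pass. With each position and strand counted once, RpL17 (0.35) and RpL12 (0.39) did not pass, nor did RpS27 with library totals (0.79) or RpL35, RpS27 and RpL12 with all deposited reads as the library size (1, 0.79 and 0.73). Of 51 nuclear genes of oxidative phosphorylation, 2 rose and 1 fell, and adjusted over the list alone 1 rose and 0 fell. ATPsynbetaL, a relative of the ATP synthase beta subunit, rose from 5 and 6 reads to 42 and 35 (log2 fold change 2.64, adjusted p = 0.00718), ATPsynE rose with 0.73, and the complex I gene ND-ASHI fell by 0.64 on the log2 scale. The median of that list was -0.13 and its camera adjusted p 0.465. The call for ATPsynbetaL was kept without any 1 library, while ATPsynE and ND-ASHI did not pass without knockdown replicate 2 (0.59 and -0.56) or knockdown replicate 1 (0.83 and -0.76), nor did ATPsynE without control replicate 2 (0.66) and ND-ASHI without control replicate 1 (-0.63). Neither passed in DESeq2, with each position and strand counted once (0.43 and -0.53) or with all deposited reads as the library size (0.61 and -0.76); nor did ATPsynE with library totals (0.63) or exact matches only (0.61), and ND-ASHI with RLE factors (-0.63), limma-voom (-0.65), no filter (-0.66) or the filter of 50 counts (-0.63).

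Some markers of muscle, stress and immunity rose in the knockdown. Of 14 genes of the muscle sheath around the ovary, 4 rose over all genes and over the list alone, and the median was 0.64. They were Zasp66, Prm, which encodes paramyosin, bt, which encodes projectin, and Msp300, with log2 fold changes of 1.56, 1.37, 1.30 and 0.83. The camera test gave an adjusted p of 0.00299, which was 0.799 with an estimated correlation. Of 9 heat shock genes, 3 rose (4 adjusted over the list alone) with a list median of 0.51. They were the co-chaperone gene stv (1.59) and the small heat shock protein genes Hsp67Ba (1.39) and Hsp67Bc (1.01). The camera test gave an adjusted p of 0.00801, which was 0.799 with an estimated correlation. Of 7 immune genes, 2 rose (4 adjusted over the list alone) with a list median of 1.09. They were Socs36E, an inhibitor of JAK/STAT signalling (log2 fold change 1.25, adjusted p = 0.0112), and the thioester protein gene Tep2 (1.17, adjusted p = 0.00976). The camera test gave an adjusted p of 0.00274, which was 0.799 with an estimated correlation. Of 3 hemocyte, fat body or gut markers tested, Col4a1, a type IV collagen gene, rose (log2 fold change 1.15, adjusted p = 0.00838), and 3 rose when adjusted over the list alone. Reads of the Wolbachia surface protein gene also followed the groups, as the plot of read classes shows. An effect of infection or strain on these markers therefore cannot be told apart from that of the knockdown. Without knockdown replicate 2 the median of the muscle list was 0.29 and its shift did not pass, and without control replicate 1 the heat shock list, at 0.38, did not pass. With each position and strand counted once, the median of the heat shock list was 0.10 and its shift did not pass. That count can rise little in abundant members, such as DnaJ-1 with 882, 904, 961 and 979 positions over 1217 covered bases. Among the genes, Zasp66 (1.11), Prm (0.80), bt (1.15), Msp300 (0.76), Hsp67Bc (0.85), Socs36E (0.94) and Tep2 (0.90) did not pass without knockdown replicate 2, nor did bt (1.02) without control replicate 1 and Msp300 (0.87) without knockdown replicate 1. DESeq2 did not call Zasp66 and bt, limma-voom did not call Prm, and with all deposited reads as the library size Zasp66, Prm, bt, Msp300, Col4a1, Hsp67Bc and Tep2 did not pass.

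Of 19 genes of DNA damage and apoptosis, 2 rose and 1 fell, over all genes and over the list alone. The caspase inhibitor gene Diap1 and the transcription factor gene Xrp1 rose with log2 fold changes of 1.17 and 0.89, and the member that fell is not reported here. The camera test of that list gave an adjusted p of 0.52. Neither Diap1 nor Xrp1 passed without knockdown replicate 2 (0.67 and 0.57) or without control replicate 1 (0.76 and 0.68), with upper-quartile factors, with library totals or with all deposited reads as the library size, and Diap1 also did not in DESeq2 or with the filter of 50 counts. Of 14 genes of paused polymerase, 0 passed in edgeR, DESeq2 or limma-voom, and 1 higher and 2 lower had an unadjusted p under 0.05 in edgeR. CycT and Spt5 gave log2 fold changes of 0.54 (adjusted p = 0.1) and 0.01, and CycT passed under some alternatives, among them without control replicate 1 (0.71). Of 3 neural and 3 testis markers, 0 passed in edgeR, DESeq2 or limma-voom, with 0 neural and 1 testis marker at an unadjusted p under 0.05; elav and fne gave 0.54 and 0.16, and twe and gdl gave -0.65 and -0.14, of which twe passed under some alternatives, among them without control replicate 2 (-0.81) and with library totals (-0.75).

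**Figure D4:**
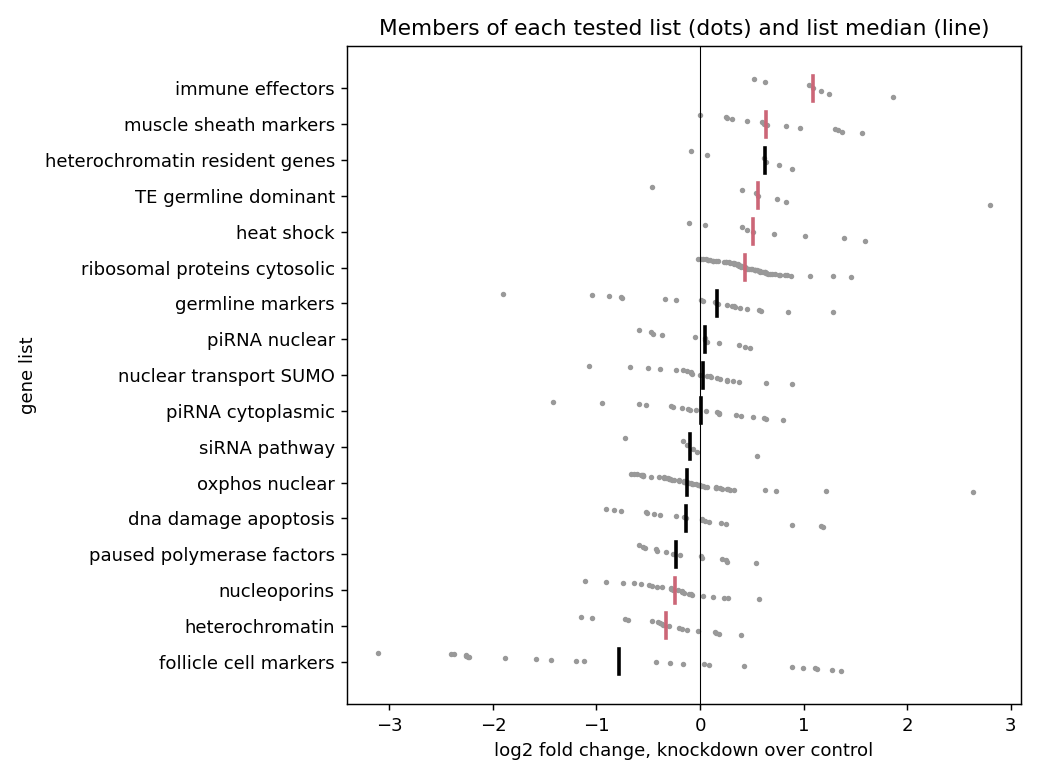
Log2 fold change (knockdown over control, horizontal axis) of each tested member (grey dots) of the 17 lists tested, with the list median as a vertical line, red where the camera test passed with a preset correlation of 0.01 and black otherwise. The medians run from -0.78 for follicle cell markers to 1.09 for immune effectors.

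Of the 17 lists with at least 5 tested members, 7 passed camera with the preset correlation, 5 upward and 2 downward. With an estimated correlation, camera called 0 of them, with 0 at an unadjusted p under 0.05 and a smallest adjusted p of 0.799. That version rests on the spread of the 4 libraries alone, so it could hardly call any list here. For the list of genes resident in heterochromatin, the camera p of this version was 0.16 against 0.0327 with the preset. The estimated correlation of that list was nevertheless -0.20. Estimated correlations of 0.74 for ribosomal proteins and 0.82 for immune effectors were far above the preset 0.01. The preset calls of such lists may therefore be too lenient. The directional fry test called 1, the list of genes resident in heterochromatin (adjusted p = 0.00367), and the mixed fry test called 12. A further 6 lists had no tested member: replication dependent histones, mitochondrial genes, snRNA, snoRNA, tRNA and rRNA.

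The genes with the largest rises were mesh, Pepck1, CG5853, Tsp42El, P5CS, CG13321, CG14829, CG8500, CG33509 and CG10970. Pepck1 (chromosome 2R, start at 14424272 in dm3) rose from 27 and 23 reads to 1793 and 1283, a log2 fold change of 5.8 (SE 0.30, adjusted p = 9.86e-06). Of its knockdown reads, 920 and 655 matched without a mismatch. The septate junction gene mesh (chromosome 3R, start at 27021484) had 0 reads in both control libraries and 11 and 124 in the knockdown libraries, at least 20-fold higher than a floor of 3 counts per library, or at least 3.3-fold without knockdown replicate 2. The tetraspanin gene Tsp42El gave a log2 fold change of 4.29, P5CS gave 4.05, and the remaining 6 lay between 3.75 and 4.35. Without 1 library, Tsp42El ran from 3.05 to 8.46 and CG14829 from 2.92 to 8.02. The genes with the largest falls were CG2187, CG13999, amd, Cp7Fc, CG4842, CG13737, CG15571, CG9449, CG15570 and CG31926. CG2187 fell from 51 and 48 reads to 0 and 4 (log2 fold change -4.69, SE 0.63, adjusted p = 0.00297), and amd fell from 198 and 196 reads to 32 and 14 (-3.23, SE 0.33, adjusted p = 0.000741). Without 1 library, the value of CG2187 ran from -8.67 to -3.77. CG4842 gave -2.92, and the lowest of these falls in size was that of CG31926, at -2.64. CG15571 and CG15570 have starts at 4111427 and 4112203 on the X chromosome, on opposite strands. Without knockdown replicate 2, CG13999 gave -2.61 and did not pass, and in DESeq2 mesh, Tsp42El, Cp7Fc and CG15570 did not pass.

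The features with the highest mean CPM were Hsp70Ba, RpL3, Cp15, Yp1 and DnaJ-1. Apart from Cp15 they did not pass the test, with log2 fold changes of 0.51, 0.01, 0.42 and 0.45 for Hsp70Ba, RpL3, Yp1 and DnaJ-1. Without control replicate 2, Hsp70Ba passed (0.74).

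Read sequences were also tested directly, without any reference. Of 110850 sequences with at least 40 reads, 6921 were higher and 176 lower in the knockdown at an adjusted p under 0.05 (edgeR). Scaling rested on these same sequences, many of them ribosomal, a class with a lower share of reads in the knockdown. How far this moved the counts of higher and lower sequences was not tested. Among the 19076 that matched none of the sequences used, 6282 were higher (32.9%) and 105 lower. The surface protein gene was the only bacterial sequence used, so other Wolbachia reads would count among these. Among 54581 from ribosomal RNA, 154 were higher and 35 lower, and among 5920 with 1 place in the windows, 39 were higher and 25 lower. Of the latter, those that matched a single gene without a mismatch, at a mean of at least 5 CPM and without overlap of the groups, came from 1 gene. The sequence with the largest change is given here. This was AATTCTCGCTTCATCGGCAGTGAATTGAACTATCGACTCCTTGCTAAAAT from Cp15 (chromosome 3L, 8722044 to 8722093 in dm3, 463 bases downstream of the start), with 53 and 175 reads in the controls and 16 and 7 in the knockdown (log2 fold change -3.51, adjusted p = 0.0367).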

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

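The 3 tests of the I-element rise given here were chosen after that result was seen. Reads of the Wolbachia surface protein gene, a gene of a bacterium that lives inside insect cells, lay outside the measurement of fly genes and were seen in the knockdown libraries above the control level. They numbered 987 and 3537 in knockdown replicates 1 and 2 and 0 in both controls, at least 244-fold and 768-fold higher than a floor of 3 counts per library. The site of a 16S rRNA primer made for Wolbachia was read 98 and 379 times in the knockdown and 0 times in both controls. A stretch conserved in bacterial 16S rRNA gave 18 and 9 reads in the controls and 1098 and 2686 in the knockdown.

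Reads of at least 25 bases without a match made up 27.3% and 36.2% of the knockdown libraries, above the 18.3% and 22.8% of the controls. Their origin was not traced, and gene parts outside the sequences used have no match either. Wolbachia sequences other than the surface protein gene were not among the sequences used. Reads that encode histone H4, which were kept out of the fit, came to 18600 and 14600 per 1e6 counted reads in the knockdown and to 11400 and 6770 in the controls. Reads that encode histone H3 went the other way, with 4810 and 4080 per 1e6 in the knockdown and 5880 and 4870 in the controls. Neither histone difference was tested.

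The I-element rise of 2.80 on the log2 scale was weighed against technical explanations. Small RNAs carried over into the libraries are argued against as its whole cause by reads of 45 to 50 bases, in which log2 of knockdown over control was 2.36, beside 3.37 in reads of 25 to 29 bases. Over 5 scaling alternatives the smallest log2 fold change was 2.67, so the choice among these did not account for the rise. They put the median of all genes between -0.14 and 0, so this test could hardly come out otherwise. Whether the assembled sequence favours I-element copies of the knockdown flies was not tested. Another strain or an infection of the knockdown flies, which might differ in I-element copies, cannot be told apart from the knockdown, since Wolbachia reads follow the groups, with at least 987 in each knockdown library. Loss of silencing after Nup358 depletion, the biological explanation that the design offers, stays open as well, while the rise lies almost wholly in reads antisense to the longest open reading frame, from 26 and 38 to 324 and 227, beside 7 and 5 to 13 and 21 sense reads (adjusted p = 0.106).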

How the results depend on the processing

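The alternatives with reads as deposited, exact matches, all deposited reads as the library size and transposon strands counted separately were chosen after the data were seen, while the other 21 of 25 were planned. Of 1330 values of named genes under an alternative, 1170 kept their direction and side of the threshold, 123 kept their direction but no longer passed, 10 newly passed and 27 reversed. Of 125 medians of the lists that passed, 106 kept direction and call, 19 lost the call and 0 reversed. The count of changed genes, 856, lay between 637 (DESeq2) and 991 (exact matches only) under RLE and upper-quartile factors, library totals, limma-voom, both filters, the library size without 20 features, reads in several genes, single positions and reads as deposited. It was 1697 with replicate number as a block, 407 with all deposited reads as the library size, and by construction 1417 and 187 at adjusted p thresholds of 0.1 and 0.01 and 178 with glmTreat. Without 1 library it ran from 328 (without knockdown replicate 2) to 1110 (without control replicate 2). Library totals moved the median of all genes to -0.11 and all deposited reads moved it to -0.14, and the share of changed genes that rose was then 40.7% and 46.9% in place of 54.1%. The 2 transposon families became 1 with library totals, 1 with all deposited reads, 6 with the block, 4 strands with strands counted separately, and 1 to 7 without 1 library. The I-element passed under all 18 alternatives run for it (2.28 to 3.03), and copia lost its call with library totals (0.73) and all deposited reads (0.70). With the block, 3 more named genes or families passed. The 7 lists became 5 with the block and 5 with reads in several genes, both upward only, 5 with single positions, 4 with the filter of 50 counts, 0 with an estimated correlation, 1 with directional fry, 12 with mixed fry, and 4 to 8 without 1 library; fry asks another question, so its counts differ by construction. The log2 fold change of Nup358 ran from -0.55 to 0.31 without 1 library and passed under no alternative. Genes that reversed were all short of the threshold in the reported fit. Upper-quartile factors gave -0.01 for Spt5 and 0 for RpL3, library totals gave -0.04 for Hel25E, -0.09 for Spt5 and -0.08 for RpL3, limma-voom gave 0 for Spt5 (below 0 before rounding), and no filter gave -0.01 for Spt5 and -0.01 for RpL3. Single positions gave -0.02 for Hel25E, -0.05 for Hsp70Ba and -0.08 for Yp1, and exact matches gave 0.09 for gdl and -0.04 for RpL3. All deposited reads gave -0.04 for Hel25E, -0.12 for Spt5 and -0.08 for RpL3. Without 1 library, Hel25E ran from -0.16 to 0.28, gdl from -0.44 to 0.07, Spt5 from -0.17 to 0.15, RpL3 from -0.20 to 0.24 and Yp1 from -0.15 to 1.34. Apart from what the construction of an alternative shows, the cause was not tested. A fit without 1 library leaves a group with a lone library, which is assumed to vary like the others. Library sizes without ribosomal, small nuclear, transfer and mitochondrial RNA were not run. Depth and spread may limit small changes, since 3.0% of genes changed 1.5-fold were called in simulation, where a smaller share of genes was changed.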

Other observations

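The 2 tests of the chorion pattern given here were chosen after that result was seen, whereas those on ribosomal proteins, neighbouring genes, chromosome 4 and the X chromosome were set before their results were seen. Lower values of the chorion genes and Fcp3C might come from fewer late egg chambers in the knockdown ovaries. This cannot be told apart from a graded effect of the knockdown on these genes. Such an effect would be indirect, since the knockdown is of germ cells and these are follicle cell genes. Across the 24 follicle cell genes, the difference between knockdown replicates 2 and 1 followed the knockdown effect with a correlation of 0.92, but the same libraries enter both quantities, and genes are not independent replicates. To ask whether a few genes taking most of the counts lowered these values, 4 scaling alternatives were run. The median of the 8 genes nearest to 0 was -2.25, so the choice among these scalings did not account for the fall. They put the median of all genes between -0.14 and 0, so this test could hardly come out otherwise.

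The positive median of the ribosomal protein genes was weighed in the same way. A trend with expression level and measured length is argued against as the whole cause, since the median log2 fold change was 0.43 before and 0.33 after the trend of all other genes was removed, with 58 of 66 genes above the trend. The weight of a single library cannot be told apart from an effect of the knockdown. The median was 0.19 without control replicate 2 and 0.75 without control replicate 1, between the bounds set for this test. A biological explanation was not tested further.

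That neighbouring genes change together was tested as a hypothesis. Among 5895 pairs of adjacent tested genes, the number that changed the same way was above a mean of 62.2 and above 77, the upper bound of the middle 95% of 10000 shuffles of the results along the genome (one-sided permutation p = 1e-04, the smallest they can give). It was made up of 57 of 2017 pairs on the same strand, against a mean of 21.2, and 45 of 3878 pairs on opposite strands, against 41 (one-sided permutation p = 0.281). Shared regulation, related copies of a gene and transcription that runs on into the next gene may each contribute, and they were not separated.

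Genes of chromosome 4, which is largely heterochromatic, did not shift as a group. Their median log2 fold change over 32 genes was -0.15, at percentile 12.3 of 10000 random gene sets matched on expression, whose middle 95% ran from -0.23 to 0.21. The median of 994 X-linked genes was -0.05, at percentile 1.6 of such sets, whose middle 95% ran from -0.05 to 0.02. The random sets treat genes as independent, although neighbouring genes changed the same way more often than in shuffles. They also do not take in the spread between libraries, and the percentiles were not adjusted for testing both chromosomes. A small downward shift of X-linked genes is thus only a hypothesis from these data, with 63 genes that rose and 84 that fell.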
